A study of Magallana hongkongensis with 2 samples.

How the data were processed

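Gene expression was measured by short-read sequencing of polyadenylated RNA from the gill of adult Hong Kong oysters (Crassostrea hongkongensis, now also called Magallana hongkongensis), an estuarine bivalve. Per the labels' protocols, wild oysters were acclimated for 2 weeks, and 1 group stayed in seawater at 23 °C while the other was moved to seawater at 37 °C for 1 h and then brought back to 23 °C. The time between the return and sampling is not given in the sources used here. Each group has 1 library. The labels say that gill from 10 oysters was pooled for the heat-shocked library and do not say how many oysters the control library holds.

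Per the submitters' processing notes, CASAVA 1.4 and cutadapt 1.8.1 were used; their roles, the aligner and the assembly of the reference transcripts are not given in the sources used here. Per the file headers, each library has 1 row per assembled transcript ("unigene") with the count of uniquely mapped reads, the length in bases, the percent of the length covered by reads, the RPKM and a description taken from the best protein match. The authors' deposited counts are whole numbers from 1, not normalized, and their sum equalled the library total printed in the header: 3925349 reads for the library labelled control and 4173215 reads for the library labelled heat shock. The deposited RPKM values equalled the count divided by the length in kilobases and by the library total, scaled as RPKM is defined, to within a relative difference of 4.9e-15, so they hold nothing beyond the counts and were not tested. The deposited coverage, in percent, was used only as a description of the libraries. The files list 20824 and 20751 unigenes, 21226 in either, and every listed unigene carries a description. The totals therefore cover the listed unigenes only. A unigene listed in 1 file only was set to 0 reads in the other; such unigenes held at most 41 reads. Lengths and descriptions of the 20349 unigenes in both files were identical.

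With 1 library per group there is no replicate check, so no p-value was computed and neither edgeR's nor DESeq2's test was run. Counts were scaled to the library total (CPM). For each unigene the ratio between libraries was given with an exact conditional binomial (Clopper-Pearson) 95% interval, which covers counting error only: PCR copies are not independent molecules, and differences between pools of oysters are not covered. It compares these 2 libraries, not the conditions. A unigene was called higher or lower when it had at least 20 reads over both libraries (17364 unigenes), a ratio of at least 2 in either direction, and an interval that excluded 1. On counts simulated for all 21226 unigenes of this comparison from the libraries' means and totals, of which 17336 passed the minimum, the rule recovered 94% of unigenes set 3-fold higher and 92% of those set 3-fold lower, recovered 100% of those set 6-fold either way, and called 113 of the 17138 unchanged unigenes that passed the minimum. The simulated counts held counting (Poisson) error only, which is what the interval assumes. The 113 is therefore no rate of false calls between the real libraries. A count of 0 allows up to 3 reads, or 0.764 CPM in the library labelled control and 0.719 in the library labelled heat shock.

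The following choices were made before the data were examined: the rule for calls, 27 gene lists and the rule for named genes. The lists were defined by words in the descriptions and covered heat shock proteins, protein folding in the endoplasmic reticulum (ER), proteolysis, apoptosis, antioxidants, immunity, translation, energy metabolism, cilia, the cell cycle and markers of other tissues or of algal food. The named genes are the 12 described unigenes with the largest and the 12 with the smallest ratio among those with at least 100 reads whose interval excluded 1, up to 3 members of each list with at least 50 reads, and common reference genes; any other gene is marked as chosen after its values were seen. For lists of 5 or more tested unigenes, the median log2 ratio (prior count 0.5) was placed among 10000 random lists of the same size, drawn with replacement from the same 10 abundance bins. This percentile describes the 2 libraries and is not a p-value; unigenes of 1 gene are not independent. It does not depend on the scaling. Lists corrected after seeing their members, families and KEGG pathways (from the deposited annotation, 10 or more tested unigenes) were added after the data were examined.

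Alternatives were edgeR's TMM factors, the median of ratios, no minimum and a minimum of 100 reads, ratios of at least 1.5 and 4, a 99.9% interval, and a prior count of 5. Alternatives planned for files with normalized values only did not apply, because counts were deposited. Unigenes are named by their best match in other species, often the Pacific oyster (Crassostrea gigas, 77.1% of listed unigenes in each library). Reads that map to several near-identical copies are absent from unique counts, and several unigenes may be pieces of 1 gene, so the split of reads within multigene families is uncertain. Genomic positions were not used here. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16 for the TMM factors.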

Results

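The series asks which genes respond to heat in the gill of the Hong Kong oyster, by comparing 1 library from oysters kept at 23 °C with 1 library from oysters shocked at 37 °C for 1 h and returned to 23 °C. The library labelled control held 3925349 uniquely mapped reads over 20824 unigenes, with a median of 46 reads per listed unigene. The library labelled heat shock held 4173215 reads over 20751 unigenes, with a median of 54. The 10 most abundant unigenes took 13.05% of the reads in the former and 11.8% in the latter. There are no replicates, so every interval given here covers counting error only, and every difference is one between these 2 libraries.

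Heat shock protein transcripts ran against the labels: they were far more abundant in the library labelled control. Heat shock protein 90, a cytosolic chaperone (Unigene0015010, 2827 bases), had 54239 reads in the library labelled control and 3478 in the library labelled heat shock, a ratio of 16.6 (95% interval 16.02 to 17.2). The inducible Heat shock protein 70 B2 (Unigene0016013) had 19995 and 321 reads, 66.2-fold more in the library labelled control (59.3 to 74.2). Heat shock protein beta-1, a small heat shock protein (Unigene0026837), had 3881 and 48 reads, a ratio of 86.0 (64.7 to 117). The 160 tested unigenes of the 5 heat shock lists together took 6.02% of the reads in the library labelled control (exact 95% interval 5.99 to 6.04%) and 0.859% in the library labelled heat shock (0.850 to 0.868%). Their summed reads were 7.003-fold higher in the library labelled control. The words of the lists missed some unigenes matched to small heat shock proteins of other animals, given below, so these sums leave them out. Because this direction goes against the labels, the libraries are called by their labels throughout.

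Over all 17364 tested unigenes, 564 were called lower and 690 higher in the library labelled heat shock. The unigenes called lower held 11.2% of the reads of the library labelled control and 1.47% of those of the other library, whereas the unigenes called higher held 0.756% and 1.90%. The median log2 ratio of all tested unigenes, heat shock label over control label, was 0.17 with library totals and 0.00 with TMM factors. With TMM factors, 758 unigenes were called lower and 406 higher, so the share of calls that were higher moved from 55.0% to 34.9%. Medians of lists are to be read against the 0.17 of all unigenes. Among the calls, 62 of the lower and 99 of the higher unigenes had only a hypothetical or uncharacterized description.

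**Figure D1:**
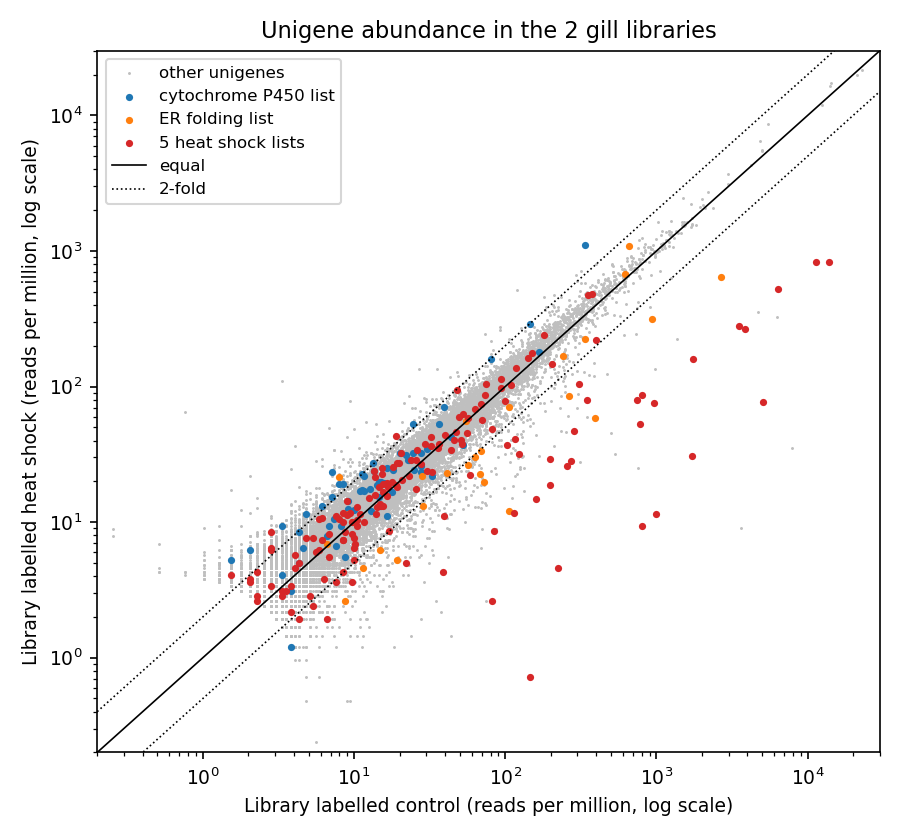
CPM (reads scaled to the library total) of each unigene with at least 20 reads over both libraries, in the library labelled control (horizontal, log scale) and the library labelled heat shock (vertical, log scale); unigenes at 0 reads in 1 library are not drawn. Many abundant members of the 5 heat shock lists (red) lie below the lower 2-fold line, and 15 of the 27 ER folding unigenes (orange, those also in a heat shock list drawn red) were called lower.

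The 12 described unigenes with the smallest ratios were chaperones and their partners, apart from a lyase and a receptor. A pair of unigenes described as Stress-induced protein 1, a small heat shock protein in nematodes, led them. Unigene0020951 had 14268 reads in the library labelled control and 38 in the library labelled heat shock, a ratio of 399 (291 to 564), and Unigene0020553 had 30876 and 147 reads, a ratio of 223 (190 to 264). Protein lethal(2)essential for life, a small heat shock protein relative in flies (Unigene0024975), had 2980 and 104 reads, a ratio of 30.5 (25.05 to 37.4). BAG family molecular chaperone regulator 4, a co-chaperone of HSP70, was 56.3-fold higher in the library labelled control (Unigene0009414, 47.3 to 67.6) and 31.2-fold higher in its other unigene (Unigene0032209, 17.2 to 63.2). A unigene of heat shock protein 70 (Unigene0009010) had 569 reads against 3, a ratio of 202 with a wide interval of 68.7 to 981. Selenocysteine lyase, which releases selenium from selenocysteine (Unigene0022327), had 291 and 11 reads, a ratio of 28.1 (15.5 to 57.0). The short unigene described as a receptor (Unigene0013477, 228 bases) had 173 and 6 reads, a ratio of 30.7 (13.8 to 84.7).

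The members of the HSP70 list differed widely in their ratios. Of its 77 tested unigenes, 13 were called lower, 5 higher and 59 neither in the library labelled heat shock. The 5 higher ones were 4 HSPA12 unigenes and Heat shock 70 kDa protein 14 (Unigene0000256, 6 and 17 reads), a ribosome-associated relative, chosen after their values were seen. Its summed reads were 8.07-fold higher in the library labelled control, while its median log2 ratio was 0.07 (percentile 4.72 of random lists) and turned to -0.10 with TMM factors. With the HSPA12 to HSPA14 members and binding partners left out, a choice made after the data were seen, all 9 remaining unigenes were called lower, with a median log2 ratio of -5.59, below all 10000 random lists. These include heat shock 70 kDa protein 4-like (Unigene0014002). The other lower calls of the HSP70 list were among the members left out. The 3 most abundant heat shock protein 70 unigenes that the fixed rule left out were 14.5-fold (Unigene0005547), 13.5-fold (Unigene0005548) and 12.6-fold (Unigene0005549) higher in the library labelled control, chosen after their values were seen; their reads may be split among pieces of 1 gene. The HSPA12 subfamily, distant relatives of HSP70 that are numerous in oysters, had 61 tested unigenes, of which 1 was called lower and 4 higher, and a median of 0.17 at percentile 49.99; this list was also added after the data were seen.

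The other chaperone lists were also higher in the library labelled control. In the small heat shock protein list, 5 of 6 tested unigenes were called lower in the library labelled heat shock, with a median log2 ratio of -3.64. Its unigenes of Alpha-crystallin B chain were 14.6-fold (Unigene0002164, 12.7 to 16.8) and 12.8-fold (Unigene0002162, 11.4 to 14.4) higher in the library labelled control. Both unigenes matched as HSP90 family were called lower, the second being the HSP90 co-chaperone Cdc37 at 6.04-fold (Unigene0017217, 5.19 to 7.07). In the HSP40 (DnaJ) list, whose proteins deliver clients to HSP70, 12 of 61 unigenes were called lower, none was called higher, and the median was -0.11. DnaJ-like protein subfamily B member 4 was 10.5-fold higher in the library labelled control (Unigene0011310, 8.29 to 13.4), and DnaJ-like protein subfamily C member 3, which sits in the ER, was 9.66-fold higher (Unigene0015577, 7.98 to 11.8). Of 16 other heat shock factors and co-chaperones, 9 were called lower and none higher, with a median of -1.99; Hsp70-binding protein 1 was 10.8-fold higher in the library labelled control (Unigene0021472, 8.29 to 14.2). The medians of the small heat shock protein, HSP40 and co-chaperone lists lay below all 10000 random lists.

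The ER folding list had 15 of 27 unigenes called lower in the library labelled heat shock and 1 called higher, protein disulfide-isomerase TMX3 (Unigene0015021, 31 and 90 reads), chosen after its values were seen. Its median log2 ratio was -1.04, below all random lists. Mesencephalic astrocyte-derived neurotrophic factor, an ER stress protein (Unigene0004445), was 8.87-fold higher in the library labelled control (6.601 to 12.1). Protein disulfide-isomerase A6 was 6.65-fold (Unigene0017553, 5.81 to 7.64) and the calcium-binding chaperone calreticulin 4.19-fold higher there (Unigene0017898, 4.02 to 4.37). The words of the list missed the ER chaperones described as 78kDa glucose regulated protein and glucose-regulated protein 94. These were 19.3-fold (Unigene0015183, 18.3 to 20.4) and 6.17-fold (Unigene0014551, 5.75 to 6.62) higher in the library labelled control, chosen after their values were seen. The transcript described as X-box binding protein-like, a regulator of the unfolded protein response (Unigene0022148), had the opposite direction at 1.65-fold higher in the library labelled heat shock (1.58 to 1.74), under the 2-fold rule. It too was chosen after its values were seen. Another regulator of this response, Eukaryotic translation initiation factor 2-alpha kinase 3, went with the chaperones. It was a named gene of the translation factor list, 2.24-fold higher in the library labelled control (Unigene0014806, 1.78 to 2.82).

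**Figure D2:**
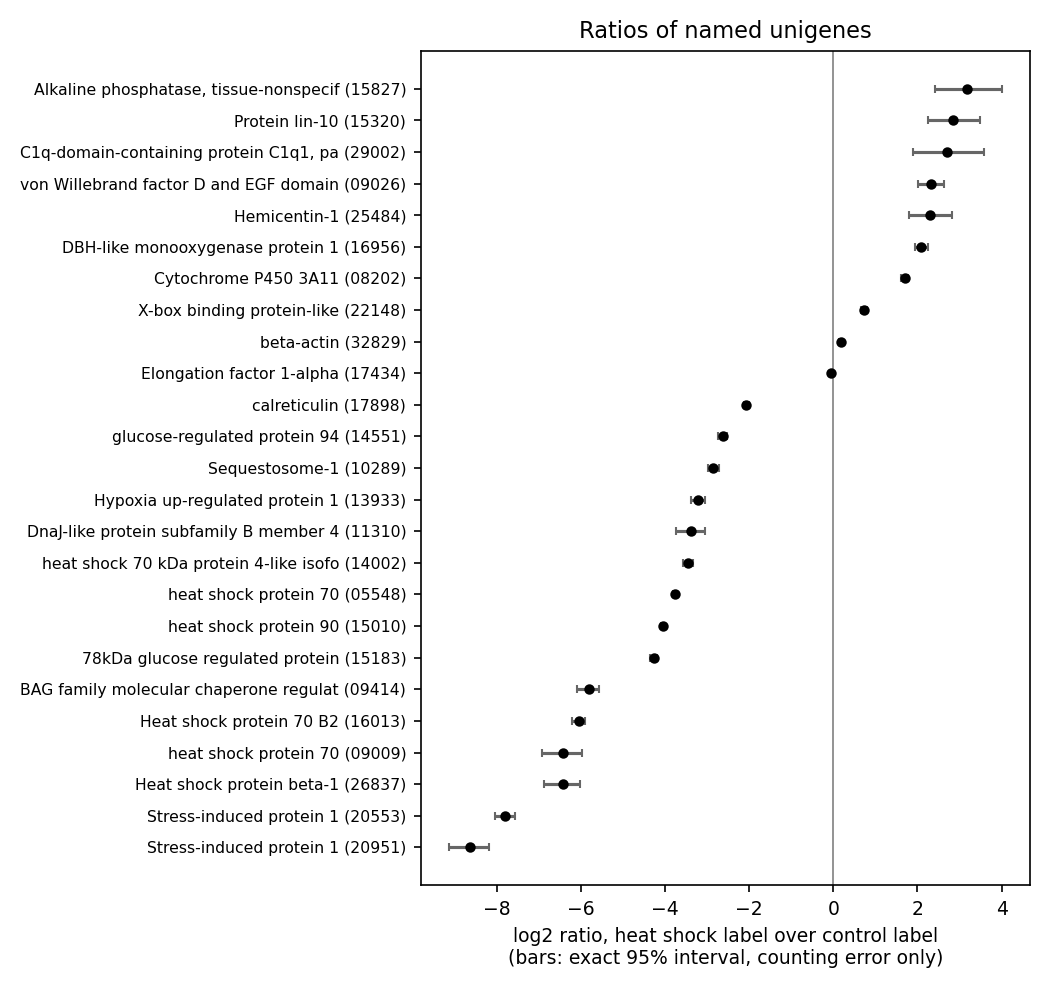
Log2 ratio of 25 unigenes, heat shock label over control label (horizontal axis), with exact 95% intervals for counting error only; the last 5 digits of each unigene name are in parentheses. Chaperones lie between Stress-induced protein 1 at -8.64 and calreticulin at -2.07, some of them chosen after their values were seen, while elongation factor 1-alpha and beta-actin lie at -0.05 and 0.18.

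Proteolysis and cell death lists held calls in both directions. Among 424 ubiquitin and proteasome unigenes, 15 were called lower and 9 higher in the library labelled heat shock, and the median of 0.14 lay at percentile 5.99. Its members with at least 50 reads whose ratios lay farthest from 1 were 3 unigenes of Ubiquitin-protein ligase E3C, from 4.90-fold (Unigene0018303, 3.64 to 6.71) to 5.57-fold higher in the library labelled control (Unigene0024752, 3.29 to 9.98). Among 143 apoptosis regulators, 14 were called lower and 10 higher, and the median of 0.04 lay at percentile 0.07; it was -0.13 with TMM factors. A unigene of Inhibitor of apoptosis protein, which blocks caspases, was 5.52-fold higher in the library labelled control (Unigene0002366, 4.29 to 7.18).

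None of the 28 unigenes caught by the words for immediate early transcription factors was called; Transcription factor AP-1 was 1.74-fold higher in the library labelled control (Unigene0019060, 1.63 to 1.86), and the list median of -0.01 lay at percentile 1.41 but was 0.11 among unigenes with at least 100 reads. The words missed the AP-1 family members described as Transforming protein v-Fos/v-Fox and Basic leucine zipper transcriptional factor ATF-like 3, and the regulator inhibitor protein kappa B. With these, an alternative added after the data were seen, 6 of 39 unigenes were called lower in the library labelled heat shock and 0 higher, with a median of -0.05 at percentile 0.14. All 6 calls came from the added descriptions, so this count and percentile rest on that choice and support nothing by themselves. Unigene0023001, a v-Fos/v-Fox unigene, had 77 and 23 reads. Among 79 antioxidant enzymes, 3 were called lower and 4 higher, with a median of 0.14 at percentile 34.0. Of 5 metallothioneins, which bind metal ions, 2 were called lower and the median was -0.53 at percentile 0.39; metallothionein IV was 5.19-fold higher in the library labelled control (Unigene0024634, 3.05 to 9.33). The 6 heme, ferritin and iron unigenes had no call and a median of 0.35 at percentile 88.3. They include a pyruvate dehydrogenase phosphatase (Unigene0016841, 37 and 65 reads), which the words caught although it is no iron gene.

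Transcripts higher in the library labelled heat shock were fewer among abundant unigenes and had smaller ratios. With at least 100 reads, 196 unigenes were called higher and 312 lower. Among the 12 described unigenes with the largest ratios, the tissue-nonspecific isozyme of Alkaline phosphatase (Unigene0015827) had 16 reads in the library labelled control and 153 in the library labelled heat shock, 8.99-fold higher (5.36 to 16.1). Protein lin-10 was 7.18-fold higher (Unigene0015320, 4.79 to 11.2) and a C1q-domain-containing protein, of a family of immune recognition proteins, 6.46-fold higher (Unigene0029002, 3.74 to 11.96). The extracellular matrix protein Hemicentin-1 was 4.90-fold higher (Unigene0025484, 3.46 to 7.09), and a von Willebrand factor D and EGF domain-containing protein 4.98-fold higher (Unigene0009026, 4.04 to 6.19). DBH-like monooxygenase protein 1 was the most abundant of the 12, with 473 and 2147 reads, a ratio of 4.27 (Unigene0016956, 3.86 to 4.73). Outside the rule, 2 hypothetical proteins had larger ratios and were chosen after their values were seen: Unigene0027227 had 3 and 271 reads, 85.0-fold higher in the library labelled heat shock (28.8 to 415), and Unigene0020538 had 13 and 462 reads, 33.4-fold higher (19.4 to 63.3).

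Cytochrome P450 monooxygenases, which oxidise lipids and foreign compounds, leaned towards the library labelled heat shock. Of 63 tested unigenes, 13 were called higher and 1 lower, and the median of 0.44 lay above all 10000 random lists. Cytochrome P450 3A11 had 1330 and 4584 reads, 3.24-fold higher in the library labelled heat shock (Unigene0008202, 3.05 to 3.45), and Cytochrome P450 26A1, of a family that breaks down retinoic acid, was 3.26-fold higher (Unigene0022970, 2.12 to 5.16). Innate immune unigenes went both ways: of 207, 18 were called lower and 17 higher, with a median of 0.08 at percentile 0.705 that turned to -0.08 with TMM factors. A C-type lectin domain family 4 member G unigene was 17.4-fold higher in the library labelled control (Unigene0029366, 8.90 to 38.7).

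Among 98 cytosolic ribosomal protein unigenes 2 were called, both higher in the library labelled heat shock; the list took 6.02% and 6.03% of the reads, and its median of 0.01 lay at percentile 0.01 and was -0.15 with TMM factors. Translation factors (median 0.15, percentile 38.4), mitochondrial respiration (0.16, percentile 50.7) and glycolysis (0.21, percentile 68.9) had 3, 3 and 1 calls among 111, 79 and 23 unigenes. Cell cycle and DNA replication unigenes had 6 called lower and 3 higher of 110 and a median of 0.28 at percentile 98.1. Of the 6, 4 were described as DNA polymerase theta, a repair polymerase, and may be pieces of 1 gene. The named unigene of these was 14.4-fold higher in the library labelled control (Unigene0024003, 7.03 to 34.1). The other calls of that list included Calcyclin-binding protein, which is no cyclin, at 5.04-fold higher in the library labelled control (Unigene0021284, 4.31 to 5.91). They also included an RNA-directed DNA polymerase of a mobile element, which is no replication enzyme of the cell. It was 4.74-fold higher in the library labelled heat shock (Unigene0009642, 3.04 to 7.69). Among the reference genes, elongation factor 1-alpha (Unigene0017434) had 48564 and 49981 reads, 1.03-fold higher in the library labelled control (1.02 to 1.05). Beta-actin was 1.13-fold (Unigene0032829, 1.11 to 1.15), Glyceraldehyde-3-phosphate dehydrogenase 1.15-fold (Unigene0019811, 1.09 to 1.22) and tubulin alpha-1A 1.21-fold higher in the library labelled heat shock (Unigene0018155, 1.20 to 1.23). Beta-tubulin was 1.16-fold (Unigene0030774, 1.15 to 1.18) and Actin 2 1.345-fold higher there (Unigene0017526, 1.296 to 1.395). Another elongation factor 1-alpha unigene picked by the rule (Unigene0025250) had 1 read in each library, too few to give a ratio, and is left out. On the log2 scale the other reference genes lay between -0.05 for elongation factor 1-alpha (Unigene0017434) and 0.43 for Actin 2, beside the 0.17 of the median unigene. Their directions were the same with TMM factors, but beta-actin came to 0.01 and Glyceraldehyde-3-phosphate dehydrogenase to 0.04, so little of their difference was left.

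Markers of other tissues and of the food algae were examined because a gill dissection can hold them. Cilia unigenes, the markers of gill epithelium, took 5.66% of the reads in the library labelled control and 6.95% in the library labelled heat shock, and their median of 0.28 lay above all random lists, with 5 of 221 called higher and 1 lower. Muscle markers had a median of 0.24 at percentile 95.6, with 8 of 118 called higher and 1 lower, and mucus cell markers one of 0.27 at percentile 94.02, with 4 of 52 called higher. Hemocyte markers had a median of 0.15 at percentile 35.7, with 6 of 85 called higher and 1 lower, all of them disintegrins or integrin-binding proteins; without those proteins, an alternative added after the data were seen, 40 unigenes had no call and a median of 0.18 at percentile 60.95. Shell and mantle markers had no call and a median of 0.09 at percentile 27.2, and digestive markers had 7 of 143 called lower and 3 higher, with a median of 0.20 at percentile 79.9. The 8 unigenes with plastid or algal words had 510 and 566 reads, 2 calls each way and a median of 0.23 at percentile 61.95. The 2 called lower (Unigene0018890 and Unigene0026290, Chlorophyllide a oxygenase) and a riboflavin biosynthesis unigene called higher (Unigene0017512) had their best matches in animals. The words therefore did not single out algal transcripts, and the list does not measure algal food. The gonad list as fixed caught every description with the word binding (729 unigenes, median 0.16, percentile 25.8); without that word its 96 unigenes had a median of 0.21 at percentile 82.1. The summed share of reads in the library labelled control, divided by that in the library labelled heat shock, lay between 0.810 for hemocyte markers and 0.983 for shell and mantle markers over the fixed lists of other tissues and algae, and was 0.795 for hemocyte markers without disintegrins and integrin-binding proteins, beside 7.003 for the 5 heat shock lists. With TMM factors, the medians of the ubiquitin, antioxidant, translation factor, respiration, hemocyte, shell and mantle and gonad lists also fell below 0, while those of the cytochrome P450, iron, glycolysis, cilia, cell cycle, muscle, mucus and digestive lists stayed above it.

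**Figure D3:**
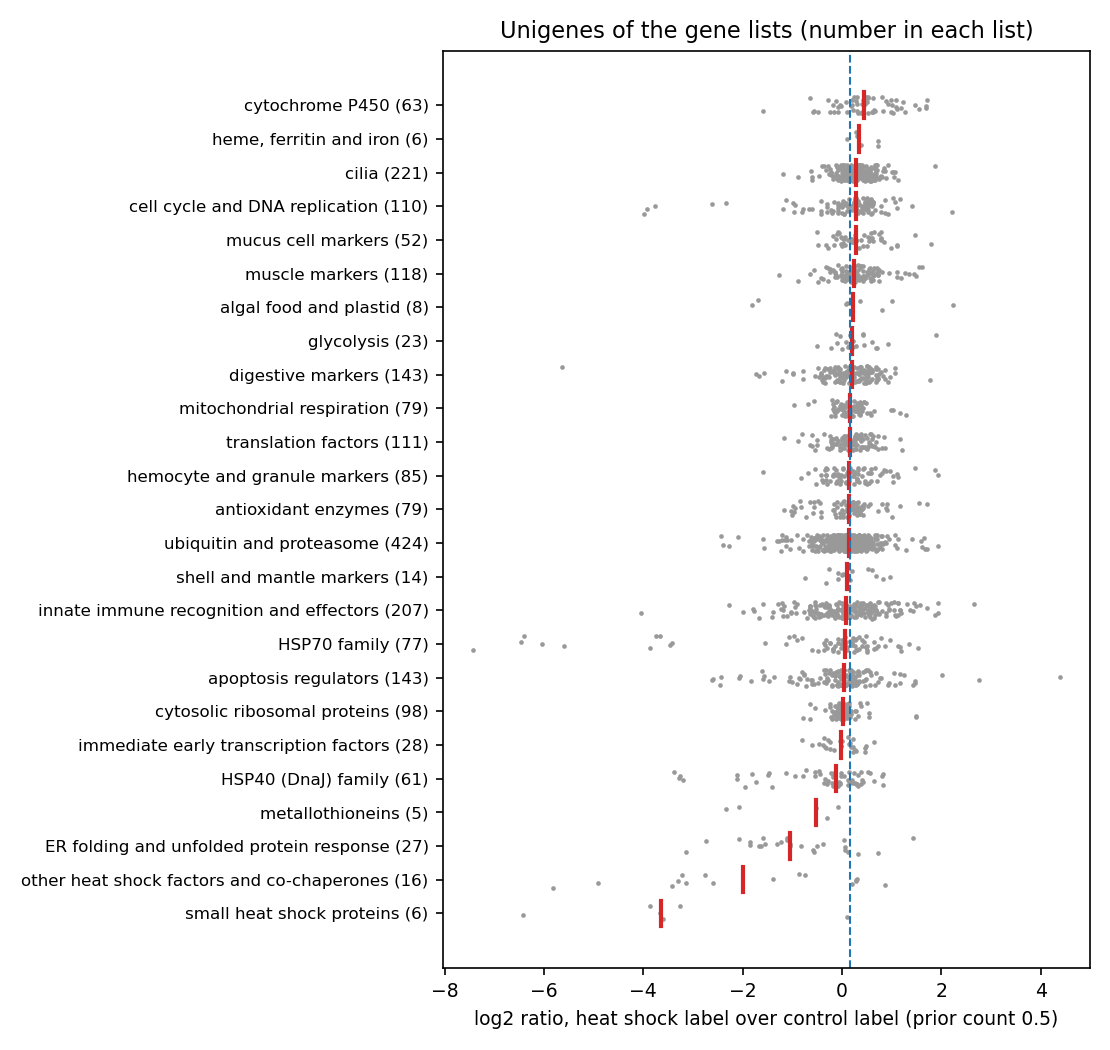
Log2 ratio of each tested unigene, heat shock label over control label (horizontal axis), in the gene lists with at least 5 tested unigenes except the gonad list; red bars mark list medians and the dashed line the median of all unigenes, 0.17. The lists with the lowest medians are small heat shock proteins at -3.64 and other heat shock factors and co-chaperones at -1.99, and the highest is cytochrome P450 at 0.44.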

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

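The library total without called unigenes and the corrected lists were chosen after seeing the data. With no replicates, no library could be left out, and no paired analysis was possible because each group has 1 library. The 690 unigenes called higher in the library labelled heat shock fell to 406 with TMM factors, 405 with the median of ratios, 427 with totals that leave out called unigenes, 315 with a stricter counting interval, 196 with at least 100 reads and 55 at 4-fold, and came to 1851 at 1.5-fold. The 564 called lower came to 312 with at least 100 reads, 141 at 4-fold and 992 at 1.5-fold, and stayed within 1.5 times 564 otherwise; all 564 were also called with TMM factors and with the median of ratios. The pseudocounts and value filters planned for files with normalized values only were not run. List medians shifted down under TMM factors and the median of ratios: HSP70 from 0.07 to -0.10 under both (-0.0958 and -0.0989), small heat shock proteins from -3.64 to -3.80 under both (-3.801 and -3.804), HSP40 from -0.11 to -0.28 under both (-0.278 and -0.281), and ER folding from -1.04 to -1.20 and -1.21. The co-chaperone median was -2.75 (-2.755) with at least 100 reads, and the HSP70 median was -5.59 without HSPA12 to HSPA14 members and binding partners. Other list medians that lay between 0 and 0.17 also crossed 0 under TMM factors and the median of ratios, as a shift of all unigenes by 0.17 does to them: apoptosis regulators (-0.126 and -0.129), innate immunity (-0.0814 and -0.0845), cytosolic ribosomal proteins (-0.155 and -0.158), and the ubiquitin, antioxidant, translation factor, respiration, hemocyte, shell and mantle and gonad lists, which came to between -0.0012 (respiration) and -0.0723 (shell and mantle) under TMM factors. The immediate early factors crossed 0 with at least 100 reads (0.11), for which the cause was not tested, and were at -0.05 with the members their words had missed. All 116 named unigenes kept their direction under TMM factors and the median of ratios. Most of them were picked for ratios far from 1, and these scalings shift every unigene alike. That result was therefore nearly fixed in advance and is no support for the directions. Depth limits unigenes with few reads: a count of 0 allows 0.764 CPM in the library labelled control.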

Other observations

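The tests of the immune pathways were written before their results were seen; the other tests and all gene families and KEGG pathways here were chosen after the data were examined. Of 218 pathways with at least 10 tested unigenes, 27 had a median below the central 95% of random lists and 27 above it, where 5.5 on each side would be reached by chance with independent lists. The highest median was that of Complement and coagulation cascades (0.69, percentile 99.99), where 1 of 12 unigenes was called higher and 0 lower. Also higher in the library labelled heat shock were Aminoacyl-tRNA biosynthesis (median log2 ratio 0.55, 1 of 33 unigenes called higher and 1 lower), Retinol metabolism (0.47, 5 of 24 called higher and 0 lower), DNA replication (0.41, 1 of 42 called higher and 0 lower) and Mismatch repair (0.41, 1 of 25 called higher and 0 lower), against 0.17 for all unigenes. By name, 32 unigenes of aminoacyl-tRNA synthetases, the enzymes that charge tRNAs with amino acids, had a median of 0.56, above all random lists, but only 1 passed the 2-fold rule. Of 11 C1q unigenes, 5 were called higher and 1 lower, with a median of 0.52 at percentile 98.0, while their summed reads had a ratio of 1.03 with an interval that held 1 (0.965 to 1.10).

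The lowest pathway median was that of Antigen processing and presentation (-1.11, 17 of 33 unigenes called lower and 1 higher). Also lower in the library labelled heat shock were protein processing in the ER (median -0.29, 44 of 173 unigenes called lower and 2 higher) and RIG-I-like receptor signaling (-0.20, 8 of 65 called lower and 0 higher). The 11 tested unigenes described as Interferon-induced helicase C domain-containing protein 1, a sensor of viral RNA, had a median of -1.22, with 7 called lower and 0 higher. Of 67 inhibitor of apoptosis unigenes, 12 were called lower and 7 higher. Sequestosome-1, an autophagy receptor, was 7.20-fold higher in the library labelled control (Unigene0010289, 6.59 to 7.88); it was chosen after its values were seen and stands for no group.

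The first pattern is that heat shock transcripts were higher in the library labelled control. The scaling of the libraries is argued against, since the summed reads of the 5 heat shock lists stayed at least 7.003-fold higher under each of the 4 scalings tried. An exchange of labels or files between the 2 libraries and a real difference as labelled, such as low chaperone expression after return to 23 °C or stress in the control oysters, cannot be told apart, because there is 1 library per group and the recovery time is not given. In 6 of the 6 heat shock and ER lists, unigenes called higher in the library labelled control were at least as many as those called higher in the other, but this is the pattern itself and both explanations predict it. Each direction above is therefore tied to the deposited labels.

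The second pattern is that the median unigene was 0.17 higher (log2) in the library labelled heat shock. A shift that depends on abundance is argued against: the medians of the 10 abundance bins lay between 0.15 and 0.20, a range of 0.0549. Reads taken up by the strongly different unigenes are a candidate explanation. The median was 0.0346 once called unigenes left the totals. Those unigenes were chosen by their ratios in these same libraries, so this value follows from their shares of reads and is no independent test.

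The third pattern is that some KEGG pathways named for immunity, Antigen processing and presentation, RIG-I-like and NOD-like receptor signaling, leaned towards the library labelled control, as did, less far, Toll-like receptor signaling (median -0.01, percentile 0.04) and Cytosolic DNA-sensing (0.03, percentile 1.37), while others did not: Complement and coagulation cascades went the other way, Primary immunodeficiency had a median of 0.46 at percentile 96.85, and Chemokine (percentile 58.4), Natural killer cell (39.96) and T cell receptor signaling (26.5) lay in the middle of random lists. Heat shock proteins are members of Antigen processing and presentation and of NOD-like receptor signaling, and were tested as the whole cause in these. Without the 5 heat shock lists, Antigen processing and presentation lost 10 of 33 unigenes. Its median moved from -1.11 to -0.32 over the remaining 23, still below all random lists. Its summed reads moved from 8.86-fold to 2.02-fold higher in the library labelled control. Those members made up much of its lean, but alone may not account for it. NOD-like receptor signaling lost only 1 of 78 unigenes, so its median could hardly move (-0.15 before, -0.14 over the remaining 77, below all random lists). The median of the remaining 77 argues against members of the 5 heat shock lists as the whole cause of the pathway's low median. The pathway's summed reads moved from 3.36-fold to 1.35-fold higher in the library labelled control, so the 1 member removed made up much of their difference. In Antigen processing and presentation, the 7 unigenes still called lower were calnexin, calreticulin, disulfide isomerases and a 68kDa heat shock protein, so chaperones outside the 5 lists stay open. In NOD-like receptor signaling, 12 of the 16 still called lower were inhibitors of apoptosis. The 31 unigenes that are not had a median of -0.16 at percentile 0.0, beside -0.08 at percentile 0.08 for the inhibitors. Among the rest, glucose-regulated protein 94 is itself an ER chaperone, and Suppressor of G2 allele of SKP1-like protein works with chaperones. A biological explanation rests on the same labels and was not tested.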
